A study of Mus musculus with 10 samples.

How the data were processed

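Poly(A)-selected RNA (oligo-dT, per the labels' protocols) from the livers of mice (strain C57B/6J, as the labels give it) aged 22 months was measured by sequencing 10 libraries, 5 of mice with floxed Arg2 alleles (Flox) and 5 of littermates lacking Arg2 in hepatocytes (LKO). The deposited values are whole-number counts of reads per Ensembl gene in 1 table, with 1 column per library and no normalization, per the file headers and the values. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread and featureCounts 1.4.6-p5 and the mouse build GRCm38, per the labels. Strandedness, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Reads shared by near-identical genes (the serum amyloid, globin, metallothionein, Cyp4a and immunoglobulin families) may therefore be lost or split, and overlapping or antisense genes cannot be separated.

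The 5 Flox columns carry the numbers of the Flox titles, 1 to 5. The 5 LKO columns are numbered 1 to 5, whereas the LKO titles run from 6 to 10, so an LKO column was used as a member of its group without a link to a title, and is called by its column number below. The table holds 55774 lines. After 287 repeats of an Ensembl identifier with identical counts were dropped, 55487 genes remained, of which 22489 had no count in any library. Total counts per library ranged from 43331354 to 54951415. At these totals a count of 0 allows up to 3 counts, or 0.0546 to 0.0692 CPM (counts scaled by the library total) per library. Floors and intervals on counts cover counting error only, since the reads carry no molecular identifiers. No 2 libraries agreed within sampling noise: over the 45 pairs, the mean chi-square per gene ranged from 41.2 to 768.

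Genes were kept with edgeR's filterByExpr at its default settings, which left 15894. Libraries were scaled by TMM (factors 0.963 to 1.04), and LKO was compared with Flox by edgeR's quasi-likelihood F test (version 4.0.16, robust fit, R 4.3.3) with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Values per library are CPM, or log2 CPM with a prior count of 2. A group value is the mean ± SD of its 5 libraries. All tests were two-sided. No label states in so many words that each library comes from a separate mouse. P-values therefore measure only the spread between these libraries, and what part of it is technical is not given.

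Before the data were examined, 48 gene lists were fixed for aged liver: arginine, polyamine and proline metabolism, senescence, inflammation, lipid, bile acid and glucose metabolism, clock, stress, xenobiotic metabolism, zonation, mitochondria, ribosome, lysosome, proliferation, tumour and matrix genes, other cell types, sex-biased genes, growth hormone axis and NAD metabolism. Of their 1145 symbols, 1142 were found and 1049 were tested. Each list was tested against all other genes with limma camera (version 3.58.1) with the inter-gene correlation preset at 0.01, adjusted over the 48 lists. Camera with an estimated correlation, and fry, which tests a list's own genes, were run beside it. A list score is the mean log2 CPM of a list's tested genes. The scores were compared by exact permutation of the 10 libraries and, for 5 lists, of the 8 libraries other than Flox 2 and 3.

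The rule for named genes was also fixed beforehand. It named Arg2, Arg1 and Rgs16, with Xist, Ddx3y and Eif2s3y as a check of sex, and up to 10 higher and 10 lower genes past the adjusted threshold whose groups did not overlap. With fewer than 10 genes past it, the rule named the 5 higher and 5 lower genes with the smallest unadjusted p at an average log2 CPM of at least 1, as values that did not pass. Within each list it named up to 4 members past the threshold over all genes or, where none passed, up to 2 with the smallest unadjusted p. Some members named by this rule are not reported here. Gene positions are those of the GENCODE M21 annotation of GRCm38, matched by Ensembl identifier. Of the 55487 identifiers, 55141 were in it.

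The fit was tested on simulated counts with the means, dispersions and library sizes of the real libraries and 200 genes changed by known folds. Of the changed genes that passed the filter, edgeR recovered 7 of 50 at 1.5-fold, 22 of 50 at 2-fold, 32 of 46 at 3-fold and 42 of 48 at 4-fold, with 5 false calls among the 15653 genes tested. DESeq2 recovered 14, 33, 40 and 45 of the same genes, with 29 false calls. With no gene changed, edgeR called 0 genes (4.47% had an unadjusted p under 0.05) and DESeq2 called 7. A list shifted by 0.5 log2 units among independent genes was recovered by camera (adjusted p = 1.33e-15, and adjusted p = 0.000488 with an estimated correlation), with 0 other lists past the threshold. In the real libraries the estimated correlation within lists had a median of 0.3, so this simulation does not show how many lists pass falsely there.

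The alternatives fixed beforehand were other scalings (DESeq2's size factors, upper quartile, library totals), DESeq2 (version 1.42.0), limma-voom with sample quality weights, other count filters, a fit without robust estimation, other thresholds, camera with an estimated correlation, fry, and leaving out each library in turn. Alternatives added after the data were seen were a fit without Flox libraries 2 and 3, fits with an acute phase, clock or erythroid score as a covariate, a fit with 2 surrogate variables (sva 3.50.0) and a fit with the column number as a block. All 10 sample columns were used. The count filter was applied anew in each fit that left out libraries, so a list's tested members, and with them its mean log2 fold change, can differ between fits.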

Results

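The study asked how loss of Arg2 from hepatocytes alters gene expression in the livers of old mice. Arg2 encodes arginase 2, the mitochondrial enzyme that splits arginine into ornithine and urea, whereas Arg1 encodes the abundant cytosolic arginase of the urea cycle. Liver RNA of mice aged 22 months on a chow diet was sequenced in 5 libraries of floxed controls (Flox) and 5 of littermates with the hepatocyte deletion (LKO). The Flox libraries held 44926666 to 54951415 gene counts and the LKO libraries 43331354 to 53891438, with 21937 to 23811 genes detected per library.

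Arg2 itself (ENSMUSG00000021125, chromosome 12, 79130777 to 79156301, GRCm38) was close to absent from the livers of both groups. The 5 Flox libraries together held 9 Arg2 counts (0.035 CPM) and the 5 LKO libraries 10 (0.042 CPM). Flox libraries 2 and 4 had 4 and 5 counts, LKO columns 4 and 5 had 4 and 6, and the other 3 libraries of each group had 0, which allows up to 3 counts each. The ratio of LKO to Flox was 1.19, with an exact 95% binomial interval of 0.434 to 3.30 that covers counting error only. It was 2.1 without Flox 4, and the direction turned without LKO column 5 (0.611), LKO column 4 (0.871), Flox 1 or 5 (0.940 each) or Flox 3 (0.979). The gene fell below the count filter and was not tested. A difference was not detectable at this depth, and these counts over the whole gene do not check the deletion. Arg1 (ENSMUSG00000019987) stood at 1127 ± 212 CPM in Flox and 1337 ± 131 CPM in LKO (SD, n = 5 each), a log2 fold change of 0.25 ± 0.15 (SE) that did not pass edgeR's quasi-likelihood test (adjusted p = 0.671). Rgs16 (ENSMUSG00000026475), a regulator of G protein signalling, varied widely in both groups, at 18.2 ± 31.2 CPM in Flox and 56.9 ± 74.9 CPM in LKO (adjusted p = 0.708). Its means were 4.29 CPM without Flox 5 and 23.8 CPM without LKO column 5. Xist had 0 to 16 counts and the Y-linked Ddx3y 1607 to 2903 counts in each of the 10 libraries, the pattern of male mice in both groups. Ddx3y and Eif2s3y had log2 fold changes of 0.40 ± 0.16 and 0.20 ± 0.12 (SE; adjusted p = 0.652 and 0.671).

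No single gene passed the comparison of LKO with Flox livers. The genes nearest to it included, on the higher side, Hbb-bs, a beta globin of red cells, Cyp4a12a, a male-biased fatty acid hydroxylase, and Bdh2, a cytosolic hydroxybutyrate dehydrogenase. On the lower side they included Atoh8, a transcription factor induced by BMP signalling, Ahr, the dioxin receptor, and Npr2, the receptor of C-type natriuretic peptide. Hbb-bs (chromosome 7, 103826534 to 103828096) was at 83.8 ± 29.4 CPM in Flox and 193 ± 61.7 in LKO (log2 fold change 1.21 ± 0.27 SE), although globin genes are near-identical and their reads uncertain. Cyp4a12a (chromosome 4, 115299046 to 115332815), which also has close copies, was at 99.3 ± 33.4 against 199 ± 44.6 CPM (1.0 ± 0.23), and Bdh2 (chromosome 3, 135281221 to 135304426) at 11.5 ± 1.6 against 17.7 ± 2.3 CPM (0.62 ± 0.13). Ctnnbip1, an inhibitor of beta-catenin, and Atp11b, a phospholipid flippase, had log2 fold changes of 0.55 ± 0.12 and 0.37 ± 0.09. Atoh8 (chromosome 6, 72206177 to 72235577) was at 30.0 ± 5.0 CPM in Flox and 15.2 ± 4.4 in LKO (-0.98 ± 0.19), and it had the smallest p of all genes (unadjusted p = 0.00020). Fam25c (-1.02 ± 0.25), Ahr (-0.64 ± 0.15), Plbd1 (-0.57 ± 0.12) and Npr2 (-0.51 ± 0.11) followed. The Flox and LKO libraries did not overlap for 9 of these 10 genes, Fam25c being the exception, but each had an adjusted p of 0.652.

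By edgeR's quasi-likelihood test 0 of 15894 genes were higher and 0 were lower in LKO at an adjusted p under 0.05, with a smallest adjusted p of 0.652. At an unadjusted p under 0.05 there were 1193 genes (504 higher and 689 lower), or 7.51%, where 795 would come by chance. That count was 575 without Flox 3, 739 without LKO column 4 and 1885 without Flox 5. The groups did not overlap for 144 genes (0.906%, with 0.794% given by chance). Limma-voom with sample quality weights also called 0 genes (1049 at an unadjusted p under 0.05). DESeq2 called 10 (1603 at an unadjusted p under 0.05): Hbb-bs, Cyp4a12a, Bdh2 and Angptl8 higher, and Atoh8, Slc13a3, Saa2, Plbd1, Fam25c and Id3 lower, at adjusted p from 0.0143 to 0.0477. Slc13a3, a dicarboxylate transporter (log2 fold change -1.67 ± 0.44 SE), lies outside the rule for named genes and was chosen after its values were seen. DESeq2 adjusted its p-values over 7704 genes after its own filter, and edgeR over 15894. On simulated counts with no change DESeq2 called 7 genes and edgeR 0. The median SE of a log2 fold change was 0.185, and edgeR recovered 22 of 50 simulated 2-fold changes and 42 of 48 simulated 4-fold changes.

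**Figure D1:**
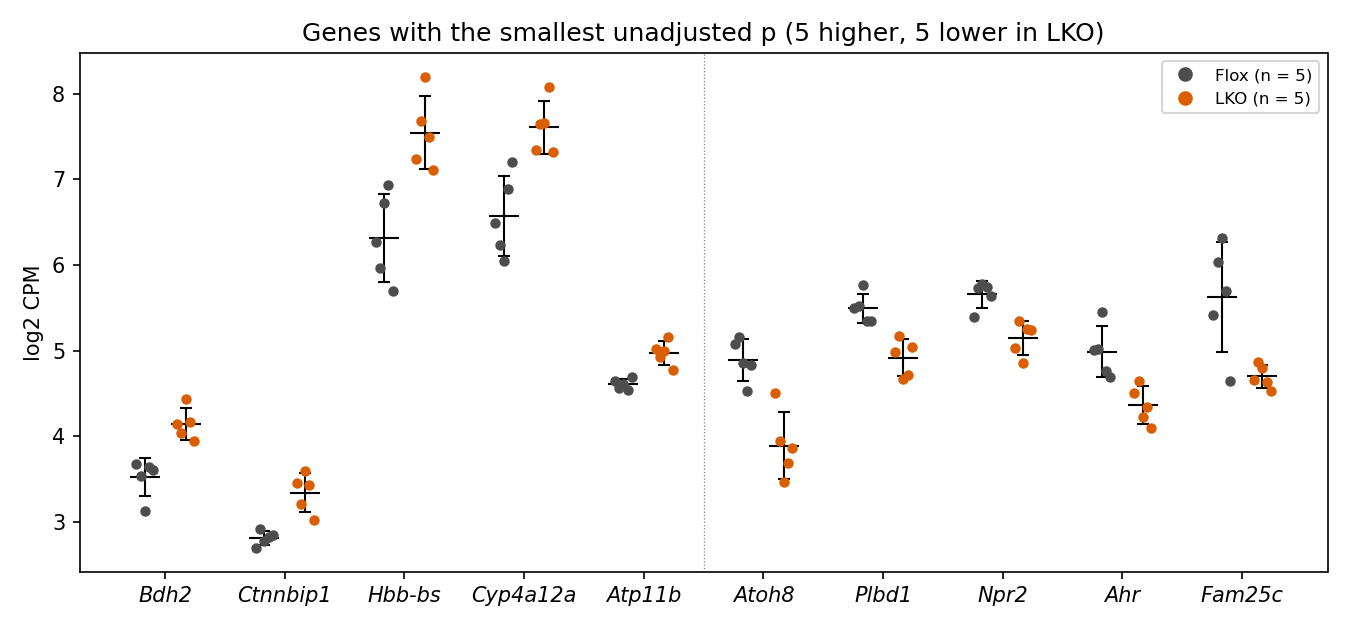
Log2 CPM (vertical axis) of the 5 higher and 5 lower genes with the smallest unadjusted p, in the 5 Flox (grey) and 5 LKO (orange) libraries. Points are libraries and bars give the mean ± SD; the groups do not overlap except for Fam25c, and no gene passed the adjusted threshold (adjusted p = 0.652 for each).

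As groups, genes of the acute phase response, interferon-stimulated genes, MHC genes and T and NK cell markers were lower in LKO, and erythroid, lipogenic and periportal genes were higher. Of the 48 lists, 29 passed camera with the correlation preset at 0.01, 15 of them higher and 14 lower in LKO. None of the 29 held with an estimated correlation, where the smallest adjusted p was 0.312, and fry called 0 lists by direction (smallest adjusted p = 0.328) and 0 for change either way (0.182). Without Flox 2 the preset correlation left 18 lists. Unadjusted, 3 lists were under 0.05 with an estimated correlation and 4 by fry. By exact permutation of the list scores 0 lists passed either (smallest adjusted p = 0.190). That test could hardly pass: its smallest possible p is 0.00794, so a single list at that p fails after adjustment over 48 lists. No member of any list passed the edgeR test adjusted over all genes, and members of 10 lists passed when adjusted over the list alone. Without Flox libraries 2 and 3, an alternative added after the data were seen, 16 of the 29 lists kept their call, 9 lost it and 4 turned in direction. The fits with covariates were likewise added. With 2 surrogate variables 9 kept it, 10 lost it and 10 turned, and with the acute phase score as a covariate 10 of 28 kept it, 9 lost it and 9 turned. Limma-voom ended 11 of the 29 calls, the clock score 7 and the erythroid score 5 of 28. The acute phase and erythroid scores themselves differed between the groups (means 8.77 and 2.27 in Flox, 7.61 and 3.21 in LKO). Group effects adjusted for these scores, here and below, therefore cannot be cleanly separated from the scores.

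All 26 acute phase genes, the liver's secreted response to inflammation, had lower values in LKO (mean log2 fold change -1.72). The list passed camera (adjusted p = 1.08e-13; adjusted p = 0.473 with an estimated correlation), while 0 members passed alone. Saa2, a serum amyloid with a near-identical copy in Saa1, was at 5320 ± 7298 CPM in Flox and 102 ± 96.9 in LKO, and Apcs at 223 ± 183 against 69.3 ± 12.1 CPM. The mean of Saa2 was 2355 CPM without Flox 3 and, in LKO, 66.1 CPM without column 2. The high values lay in 3 Flox libraries: Saa1 and Saa2 took 1.72%, 3.43% and 0.394% of all counts in Flox 2, 3 and 4, and at most 0.0803% in the other 7 libraries. The mean log2 fold change was -1.11 without Flox 3. Without Flox libraries 2 and 3 it was -0.48 and the list still passed camera (adjusted p = 0.0360), whereas with 2 surrogate variables it did not (mean -0.10, adjusted p = 0.128). With the erythroid score the mean was -2.78. The metallothioneins Mt1 and Mt2, in the list of NRF2 targets and oxidative stress defence, had similar profiles, with Mt1 at 730 ± 1028 against 48.9 ± 32.9 CPM (301.5 CPM in Flox without library 3). That list did not pass (15 of 27 higher, adjusted p = 0.295), except without Flox 1 (0.0270, on the higher side).

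Interferon-stimulated genes were lower in LKO for 33 of 34 members (mean log2 fold change -0.84; adjusted p = 4.84e-11, and adjusted p = 0.473 with an estimated correlation). Irf9, part of the interferon-activated transcription complex, was at 48.2 ± 4.0 CPM in Flox and 36.1 ± 6.8 in LKO, and its partner Stat2 at 62.2 ± 15.9 against 43.7 ± 8.0 CPM. All 13 MHC class II genes were lower (mean -1.06; adjusted p = 1.43e-09, and adjusted p = 0.473 with an estimated correlation), and 7 of them passed when adjusted over the list alone. H2-Ab1 was at 61.0 ± 44.6 against 21.3 ± 9.1 CPM and H2-Eb1 at 42.5 ± 34.8 against 14.5 ± 6.4 CPM. All 19 MHC class I genes were lower (mean -0.54; adjusted p = 3.07e-07, and adjusted p = 0.473 with an estimated correlation), among them Tap1, the peptide transporter, at 62.9 ± 50.4 against 28.8 ± 6.8 CPM and the class I transactivator Nlrc5 at 19.2 ± 6.1 against 12.7 ± 3.2 CPM. Flox library 3 had the highest score of all 10 libraries in each of these 3 lists, and without it the Flox means of H2-Eb1 and Tap1 were 27.0 and 41.2 CPM and the lists' mean log2 fold changes -0.41, -0.63 and -0.27. Without Flox libraries 2 and 3 these means were -0.53, -0.74 and -0.36, with the acute phase score -0.30, -0.56 and -0.18, and with 2 surrogate variables, where the MHC class I list did not pass (0.147), -0.19, -0.47 and -0.12. With the erythroid score the interferon mean was -1.79 and the MHC class I mean -1.08.

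Markers of several immune cells were lower in LKO beside these genes. T and NK cell markers were lower for 20 of 22 members (mean -0.85; adjusted p = 2.33e-09, and adjusted p = 0.473 with an estimated correlation). Lck, the kinase of the T cell receptor, was at 1.20 ± 0.62 against 0.410 ± 0.101 CPM and passed when adjusted over the list alone, and Il2rb was at 2.02 ± 1.07 against 0.880 ± 0.187 CPM. The T and NK list did not pass with 2 surrogate variables (mean -0.13, adjusted p = 0.151), and its mean was -0.25 with the acute phase score and -1.43 with the erythroid score. Markers of recruited and lipid-associated macrophages were lower for 16 of 20 members (adjusted p = 0.00259, and adjusted p = 0.575 with an estimated correlation). Ccr2 was at 3.19 ± 2.46 against 1.11 ± 0.38 CPM and Itgax at 1.49 ± 0.80 against 0.626 ± 0.286 CPM. Without Flox 3 the Flox mean of Ccr2 was 2.11 CPM. The call ended without Flox 4 (0.0615) or LKO column 1 (0.130) and with the acute phase score (0.585), and the test lay on the higher side with 2 surrogate variables (0.701). Kupffer cell markers were lower for 16 of 18 members (adjusted p = 0.0387, and adjusted p = 0.612 with an estimated correlation), including Id3 (58.9 ± 25.5 against 27.8 ± 4.4 CPM), which hepatocytes also express and which passed alone when adjusted over the list alone. Slc40a1, the iron exporter, was on the other side (49.3 ± 18.6 against 63.4 ± 5.4 CPM). Without Flox 4 the Kupffer list lay on the higher side (0.861), and its call ended without Flox 2 or LKO columns 1, 4 or 5 (0.0585 to 0.673). Limma-voom (0.130) and library totals (0.0810) also ended it, and it lay on the higher side with the acute phase score (0.585) and past the threshold there with 2 surrogate variables (0.00117). Neutrophil markers, with Lcn2 (943 ± 1406 against 61.8 ± 70.1 CPM), which hepatocytes make in the acute phase, and Elane, did not pass (adjusted p = 0.0584). They passed on the lower side without Flox 5 (0.00385) or LKO column 2 (0.00178) and with the erythroid score (1.25e-08), and on the higher side with 2 surrogate variables (0.00487). The Flox mean of Lcn2 was 331 CPM without library 3, and its LKO mean 31.4 CPM without column 2. Neither did B and plasma cell markers pass (0.934). Ighg1 was at 22.7 ± 41.8 against 2.0 ± 1.52 CPM and Ighg2c at 9.23 ± 5.31 against 5.48 ± 1.93 CPM, but the Flox mean of Ighg1 was 4.16 CPM without library 5. The B and plasma cell list was lower without Flox 2 and 3 (0.00162) and with the clock score (0.0358).

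**Figure D2:**
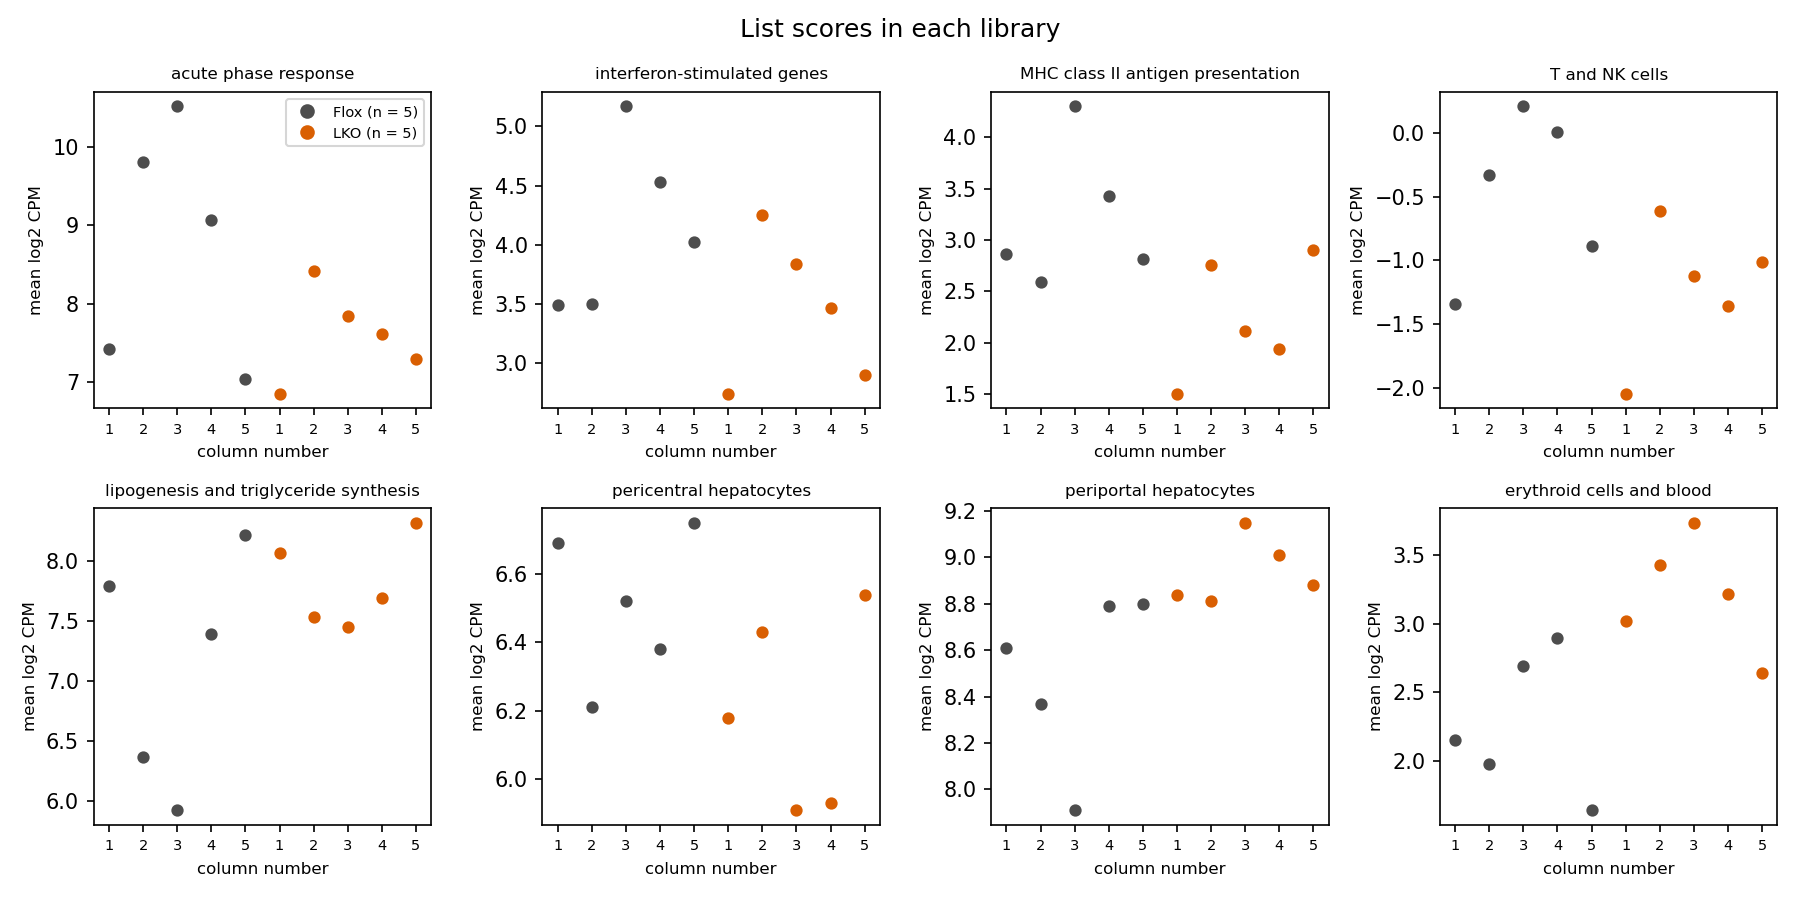
List scores (mean log2 CPM of each list's genes, vertical axes) in each Flox (grey) and LKO (orange) library, by column number, for 8 lists. The acute phase score is highest in Flox 3 (10.52), Flox 2 (9.81) and Flox 4 (9.07), lipogenesis is lowest in Flox 3 (5.92) and Flox 2 (6.36), and the erythroid scores are 1.64 to 2.90 in Flox and 2.64 to 3.74 in LKO.

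All 11 tested genes of the list of erythroid cells and blood, called erythroid here, were higher in LKO (mean log2 fold change 0.93; adjusted p = 5.62e-13, and adjusted p = 0.312 with an estimated correlation), and 7 passed when adjusted over the list alone. The list also holds the platelet genes Pf4 and Ppbp. Hbb-bs had the smallest p among them. The score was 2.27 ± 0.51 in Flox and 3.21 ± 0.42 in LKO (SD, n = 5; exact permutation p = 0.0238, adjusted 0.381 over the 48 lists).

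The lists of the 2 ends of the liver lobule had mean log2 fold changes of opposite sign, and the opposition itself was not tested. Periportal genes were higher in LKO for 18 of 20 members (mean 0.43; adjusted p = 5.74e-08, and adjusted p = 0.473 with an estimated correlation). Hsd17b13, a lipid droplet protein, was at 306 ± 46.7 against 425 ± 45.9 CPM and Aldh1b1, a mitochondrial aldehyde dehydrogenase, at 64.3 ± 22.6 against 120 ± 32.7 CPM. The 5 LKO scores (8.81 to 9.15) lay above the 5 Flox scores (7.91 to 8.80), at the smallest p an exact permutation of 5 against 5 allows (0.00794, adjusted 0.190). The muscle list of 3 genes, which did not pass camera, reached the same p. Without Flox 2 and 3 the mean was 0.24. Pericentral genes were lower for 16 of 20 members (mean -0.34; adjusted p = 2.47e-06, and adjusted p = 0.473 with an estimated correlation). The Wnt target genes Lgr5 (5.85 ± 1.29 against 3.57 ± 0.83 CPM) and Axin2 (9.34 ± 3.45 against 5.07 ± 1.4 CPM) had the smallest p among them. For each of these lists 2 members passed when adjusted over the list alone. The pericentral call ended with the erythroid score as a covariate (mean -0.10, adjusted p = 0.319). General hepatocyte genes did not pass (17 of 27 higher, adjusted p = 0.134). Alb, albumin, was at 70400 ± 23840 against 108200 ± 8701 CPM and Tdo2 at 723 ± 153 against 967 ± 118 CPM. Endothelial markers were lower (13 of 22; adjusted p = 0.0243, and adjusted p = 0.606 with an estimated correlation), led by the sinusoidal lectin Clec4g (24.4 ± 5.3 against 17.5 ± 2.9 CPM) and Egfl7. This call ended without Flox 1 or 4 or LKO columns 1 or 3 (0.0673 to 0.336), with 2 surrogate variables (0.193) and with the column number as a block (0.0514).

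Lipogenic genes were higher in LKO for 25 of 27 members (mean 0.41; adjusted p = 2.47e-06, and adjusted p = 0.606 with an estimated correlation), although none reached an unadjusted p under 0.05. Pklr, liver pyruvate kinase, was at 177 ± 134 against 310 ± 137 CPM and Acaca, acetyl-CoA carboxylase, at 112 ± 58.1 against 158 ± 36.2 CPM. The lowest lipogenic scores were those of Flox 2 and 3, the libraries with the highest acute phase scores, and without these 2 libraries the list did not pass and the test lay on the lower side (adjusted p = 0.876), as it did with the acute phase score (0.440). The call also ended with 2 surrogate variables (0.104). The mean was 0.25 without Flox 2, 0.23 without Flox 3, 0.26 without LKO column 5 and 0.73 without Flox 5. It was 1.15 with the erythroid score and 0.65 with the column number as a block. Genes of lipid droplets and uptake were higher for 19 of 24 members (adjusted p = 0.0194, and adjusted p = 0.606 with an estimated correlation), with lipoprotein lipase, Lpl, at 18.3 ± 8.7 against 41.9 ± 29.1 CPM and Fabp4 at 6.15 ± 2.53 against 9.25 ± 2.02 CPM. That call ended without Flox 2 or 4 or LKO columns 1 or 5 (0.152 to 0.512) or without Flox 2 and 3 together (0.291). It also ended with limma-voom (0.123) and the clock score (0.0797), and the direction turned with the acute phase score (0.758) and 2 surrogate variables (0.764). Bile acid genes were higher for 20 of 24 members (adjusted p = 0.00259, and adjusted p = 0.473 with an estimated correlation). Akr1d1 was at 89.9 ± 33.1 against 125 ± 20.9 CPM and the sterol transporter Abcg5 at 39.5 ± 12.5 against 56.5 ± 19.4 CPM. The bile acid list did not pass without Flox 2 and 3 (0.271), with the acute phase score as a covariate (0.610) or with 2 surrogate variables (0.553). Cholesterol synthesis genes did not pass (adjusted p = 0.934). Srebf2 was at 93.8 ± 6.4 against 79.5 ± 9.7 CPM. The list was lower without Flox 3 (0.000143), without Flox 2 and 3 (5.23e-09), with the acute phase score (1.29e-06) and with 2 surrogate variables (0.00304), and higher with the erythroid score (0.00708). PPAR-alpha targets did not pass (adjusted p = 0.303). Ucp2 was at 36.4 ± 14.7 against 24.5 ± 8.0 CPM and Angptl4 at 54.0 ± 20.9 against 38.4 ± 14.4 CPM. The list passed on the higher side without Flox 1 or 5 or LKO columns 3 or 4 (0.0190 to 0.0370), with the erythroid score (7.64e-11) and with the column number as a block (0.0453). It passed on the lower side with the acute phase score (0.0194) and 2 surrogate variables (0.00117), and lay there, not past the threshold, without Flox 4 or LKO columns 1 or 5 (0.371 to 0.785). Genes of glucose handling did not pass either (16 of 23 higher, adjusted p = 0.0584), and the members with the smallest p were lower: Igfbp1 at 57.2 ± 79.7 against 15.2 ± 2.7 CPM and Pck1, the gluconeogenic carboxykinase, at 1910 ± 464 against 1383 ± 286 CPM. Without Flox 1 the Flox mean of Igfbp1 was 21.9 CPM. That list passed, on the higher side, without Flox 1 or 5 or LKO columns 2, 3 or 4 (0.00892 to 0.0426), with the erythroid score (0.000225), with the column number as a block (0.00546) and without a count filter (0.0240).

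Among the pathways that use arginine or its products, genes of the urea cycle and arginine handling were slightly higher in LKO (12 of 19; mean log2 fold change 0.10; adjusted p = 0.0387, and adjusted p = 0.606 with an estimated correlation). Otc, which joins ornithine to carbamoyl phosphate, was at 314 ± 69.9 CPM in Flox and 426 ± 44.6 in LKO, and Ddah1 at 129 ± 43 against 171 ± 16 CPM. The call ended without Flox 2, 3 or 4 or LKO columns 1, 3 or 5 (0.0619 to 0.306), and without Flox 2 and 3 together (0.904), where the mean was -0.02. It also ended with limma-voom (0.0810), no count filter (0.0530), the clock score (0.0679) and 2 surrogate variables (0.750), and the list lay on the lower side with the acute phase score (mean -0.03, adjusted p = 0.930). The mean lay between 0.01 and 0.04 without Flox 1, 2 or 5 or LKO column 2 and between -0.02 and 0 without LKO columns 1, 3 or 5. Each of these means covers the members that passed the count filter in that fit, so it does not measure the weight of the omitted library alone. Polyamine genes did not pass (10 of 18 higher, adjusted p = 0.605). Mtap was at 14.4 ± 1.2 against 17.4 ± 2.2 CPM and Azin1 at 48.3 ± 9.6 against 59.1 ± 7.4 CPM. Neither did genes of proline, glutamate and glutamine metabolism (8 of 17 higher, adjusted p = 0.919). Gls2 was at 289 ± 90.7 against 412 ± 75.9 CPM and Slc1a2 at 130 ± 28.4 against 95.4 ± 31.4 CPM.

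Of the lists on ageing and damage, secreted senescence factors were lower in LKO (18 of 24; mean -0.45; adjusted p = 0.0387, and adjusted p = 0.554 with an estimated correlation). Csf1 was at 10.2 ± 2.2 against 7.15 ± 1.85 CPM and Plau at 1.07 ± 0.45 against 0.590 ± 0.204 CPM. The call ended without Flox 3 (mean -0.28) or 4 or LKO column 1 (0.0841 to 0.151), with limma-voom (0.106), library totals (0.0767) and the acute phase score (0.585). It turned in direction with 2 surrogate variables (0.935), and the mean was -0.29 without Flox 2 and 3. Senescence and cell cycle inhibitors did not pass (9 of 16 higher, adjusted p = 0.837; Bcl2l1 34.5 ± 3.4 against 29.7 ± 2.8 CPM, Bmi1 13.6 ± 0.8 against 15.7 ± 2.0 CPM). Neither did p53 targets (16 of 23 lower, adjusted p = 0.303; Fas 21.0 ± 8.6 against 14.03 ± 3.4 CPM, Gadd45b 1.98 ± 2.15 against 0.875 ± 0.277 CPM). Without Flox 3 the Flox mean of Gadd45b was 1.03 CPM. Proliferation genes were lower for 28 of 40 members (adjusted p = 0.0387, and adjusted p = 0.612 with an estimated correlation). Top2a was at 2.73 ± 1.47 against 1.19 ± 0.54 CPM and Tpx2 at 0.830 ± 0.404 against 0.326 ± 0.188 CPM. This call ended without Flox 3, 4 or 5 or LKO columns 1 or 4 (0.0854 to 0.496), with limma-voom (0.0902), library totals (0.0810) and the acute phase score (0.679), and turned with 2 surrogate variables (0.349). Tumour and oncofetal genes were higher for 9 of 13 members (adjusted p = 0.0387, and adjusted p = 0.473 with an estimated correlation), with the imprinted H19 at 0.312 ± 0.217 against 1.4 ± 1.68 CPM and Tff3 at 3.03 ± 4.0 against 24.4 ± 30.5 CPM. The LKO mean of H19 was 0.667 CPM without column 5, and the means of Tff3 were 1.27 CPM without Flox 4 and 11.3 CPM without LKO column 3. The tumour list lost its call without Flox 2 or 3 or LKO columns 2, 3 or 5 (0.0518 to 0.167), and without Flox 2 and 3 together (0.705). So it did with limma-voom (0.152) and the acute phase (0.316), clock (0.148) and erythroid scores (0.287).

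Genes of the unfolded protein response were lower for 26 of 31 members (adjusted p = 0.0254, and adjusted p = 0.612 with an estimated correlation). Ddit3 was at 5.17 ± 1.76 against 3.64 ± 0.40 CPM and the chaperone Calr at 1219 ± 389 against 941 ± 119 CPM. The call ended without Flox 2 or 3 or LKO columns 1 or 5 (0.0873 to 0.819), and without Flox 2 and 3 together the list passed on the higher side (0.0380), as it did with the acute phase score (0.0375). Limma-voom (0.474) and the clock score (0.361) ended the call, and 2 surrogate variables turned its direction (0.701). Heat shock genes were lower for 12 of 16 members (adjusted p = 0.0387, and adjusted p = 0.606 with an estimated correlation). Bag3 was at 66.3 ± 8.1 against 51.5 ± 6.9 CPM and Hspb8 at 242 ± 108 against 144 ± 18.1 CPM. Omitting a library ended the call in 7 of 10 cases (Flox 2, 3 or 4, LKO columns 1, 2, 3 or 5; 0.0552 to 0.195), as did leaving out Flox 2 and 3 together (0.786), limma-voom (0.0683), the clock score (0.120) and 2 surrogate variables (0.689). The acute phase score turned its direction (0.889). Xenobiotic genes were higher for 21 of 28 members (adjusted p = 0.0387, and adjusted p = 0.606 with an estimated correlation), while the dioxin receptor Ahr, the only member past the threshold over the list alone, and Cyp3a13 (196 ± 77.8 against 132 ± 18.2 CPM) were lower. This call ended without Flox 2, 3 or 4 or LKO columns 1, 2 or 5 (0.108 to 0.381), with limma-voom (0.139) and with the clock score (0.0797). The test lay on the lower side without Flox 2 and 3 (0.690), with the acute phase score (0.542) and with 2 surrogate variables (0.689). Clock and fasting genes were higher for 17 of 22 members (adjusted p = 0.0132, and adjusted p = 0.473 with an estimated correlation), with the repressors Nr1d1 at 58.7 ± 41.3 against 89.6 ± 6.4 CPM and Nfil3 at 42.2 ± 27.8 against 21.9 ± 11.6 CPM. Arntl and Npas2 also had lower values in LKO (log2 fold changes -0.48 and -0.68), and Dbp and Per3 higher ones (0.65 and 0.43). The call is thus not a common shift of all clock genes. The call ended without Flox 2 (0.0621), LKO column 5 (0.108) or Flox 2 and 3 together (0.368) and with the acute phase score (0.364).

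Nuclear genes of the respiratory chain were higher for 45 of 53 members, by little (mean 0.11; adjusted p = 0.000208, and adjusted p = 0.606 with an estimated correlation). Ndufs1 was at 71.9 ± 14.7 against 89.0 ± 8.0 CPM and Uqcrfs1 at 126 ± 15.9 against 144 ± 5.8 CPM. The respiratory chain list did not pass with the acute phase score (0.930), and lay on the lower side with 2 surrogate variables (0.699). Its mean was 0.07 without Flox 3 or 4 or LKO column 1 and 0.05 without Flox 2 and 3. All 15 mitochondrially encoded transcripts were higher (mean 0.25; adjusted p = 0.00424, and adjusted p = 0.606 with an estimated correlation). mt-Rnr2 was at 1420 ± 102 against 1736 ± 390 CPM and mt-Nd3 at 20.1 ± 2.9 against 25.9 ± 12.7 CPM. Mitochondrial genes took 3.12% to 8.31% of counts in Flox and 4.64% to 8.38% in LKO libraries. The call of the mitochondrially encoded list ended without Flox 2 (mean 0.14, adjusted p = 0.169), LKO column 4 (0.07, 0.168) or Flox 2 and 3 together (0.02, 0.926) and with limma-voom (0.118). It turned with the acute phase score (0.832) and 2 surrogate variables (0.791), and the mean was 0.46 without Flox 1. Ribosomal protein genes were lower for 61 of 75 members (mean -0.06; adjusted p = 0.0126, and adjusted p = 0.606 with an estimated correlation). Rplp2 was at 220 ± 34.5 against 184 ± 15.8 CPM and Rpl13a at 12.3 ± 1.6 against 10.2 ± 1.7 CPM. This call ended without Flox 2 (mean -0.03, adjusted p = 0.131), LKO column 3 (0.0717) or Flox 2 and 3 together (mean -0.02, adjusted p = 0.364), and with the acute phase score (0.324), the erythroid score (0.193) or 2 surrogate variables (0.151). Lysosome and autophagy genes did not pass (adjusted p = 0.934; Atp6v1h 38.0 ± 2.4 against 43.6 ± 0.8 CPM, Map1lc3b 102 ± 15.6 against 83.7 ± 7.8 CPM).

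Stellate cell and myofibroblast markers were higher for 11 of 16 members (mean 0.29; adjusted p = 0.0110, and adjusted p = 0.606 with an estimated correlation). Rgs5, a pericyte gene, was at 13.3 ± 4.1 against 23.4 ± 4.5 CPM and the smooth muscle actin Acta2 at 1.45 ± 0.72 against 4.06 ± 3.10 CPM (2.70 CPM in LKO without column 3). The call ended without Flox 2 (mean 0.17) or 3 or LKO column 5 (0.0661 to 0.234), with limma-voom (0.172) and with the clock score (0.0797), and the mean was 0.46 without Flox 5. The test lay on the lower side without Flox 2 and 3 (mean -0.01, adjusted p = 0.656), with the acute phase score (0.293) and with 2 surrogate variables (0.935). Matrix genes did not pass (adjusted p = 0.919), but did on the lower side without Flox 2 and 3 (0.00296), with the acute phase score (0.000158) and with 2 surrogate variables (0.0251). Postn was at 2.89 ± 1.63 against 6.90 ± 1.87 CPM and Tgfb2 at 0.223 ± 0.049 against 0.497 ± 0.142 CPM. Muscle markers (3 genes; adjusted p = 0.0973) held Myh11, the myosin of smooth muscle, at 1.51 ± 0.63 against 5.42 ± 3.30 CPM, which passed over the list alone, and Des at 7.10 ± 0.84 against 6.60 ± 0.72 CPM. The list passed without LKO column 1 (0.0466) or 4 (0.0487). Markers of cholangiocytes (adjusted p = 0.295; Elf3 1.52 ± 1.4 against 0.667 ± 0.343 CPM, Krt19 0.680 ± 0.285 against 1.10 ± 0.46 CPM), of adipocytes and mesothelium (0.71; Krt8 393 ± 51.2 against 334 ± 32.4 CPM) and of exocrine pancreas and gut (0.304; Amy2b 0.618 ± 0.153 against 0.848 ± 0.088 CPM, Cela1 17.1 ± 5.1 against 17.6 ± 1.6 CPM) did not pass. Without Flox 3 the Flox mean of Elf3 was 0.906 CPM. The adipocyte and mesothelium list was lower with 2 surrogate variables (0.000969).

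Male-biased liver genes (21 of 26; mean 0.60; adjusted p = 0.00012, and adjusted p = 0.606 with an estimated correlation) and female-biased ones (19 of 26; mean 0.46; adjusted p = 0.000208, and adjusted p = 0.554 with an estimated correlation) were both higher in LKO. Cyp4a12a, which passed over the list alone, and Keg1 (67.0 ± 15.6 against 92.3 ± 20.5 CPM) led the first. The second held Fmo4 (5.64 ± 2.37 against 9.74 ± 2.01 CPM) and, on the lower side, Gas6 (163 ± 114 against 68.3 ± 20.4 CPM). The male-biased call ended without LKO column 4 (mean 0.31, adjusted p = 0.0514) and with the erythroid score (0.346). The female-biased call ended without Flox 2 and 3 (0.0779), with the acute phase score (0.474) and with 2 surrogate variables (0.161); its mean was 0.27 without Flox 2, 0.18 without LKO column 5 and 0.26 without Flox 2 and 3. The 4 measured sex chromosome genes, all Y-linked, were higher (mean 0.29; adjusted p = 0.00771, and adjusted p = 0.473 with an estimated correlation). Uty was at 7.03 ± 1.16 against 8.79 ± 1.83 CPM. That call ended without a count filter (0.120) and with the erythroid score (0.135). Genes of the growth hormone axis and hepatokines did not pass (adjusted p = 0.636). Angptl8, an insulin-induced inhibitor of lipoprotein lipase, was at 52.5 ± 16.4 against 96.7 ± 17.1 CPM, past the threshold over the list alone, and Hamp, the iron hormone hepcidin, at 841 ± 84.2 against 465 ± 223 CPM. Neither did NAD metabolism and sirtuin genes (0.352; Naprt 137 ± 31.5 against 102 ± 11.3 CPM).

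**Figure D3:**
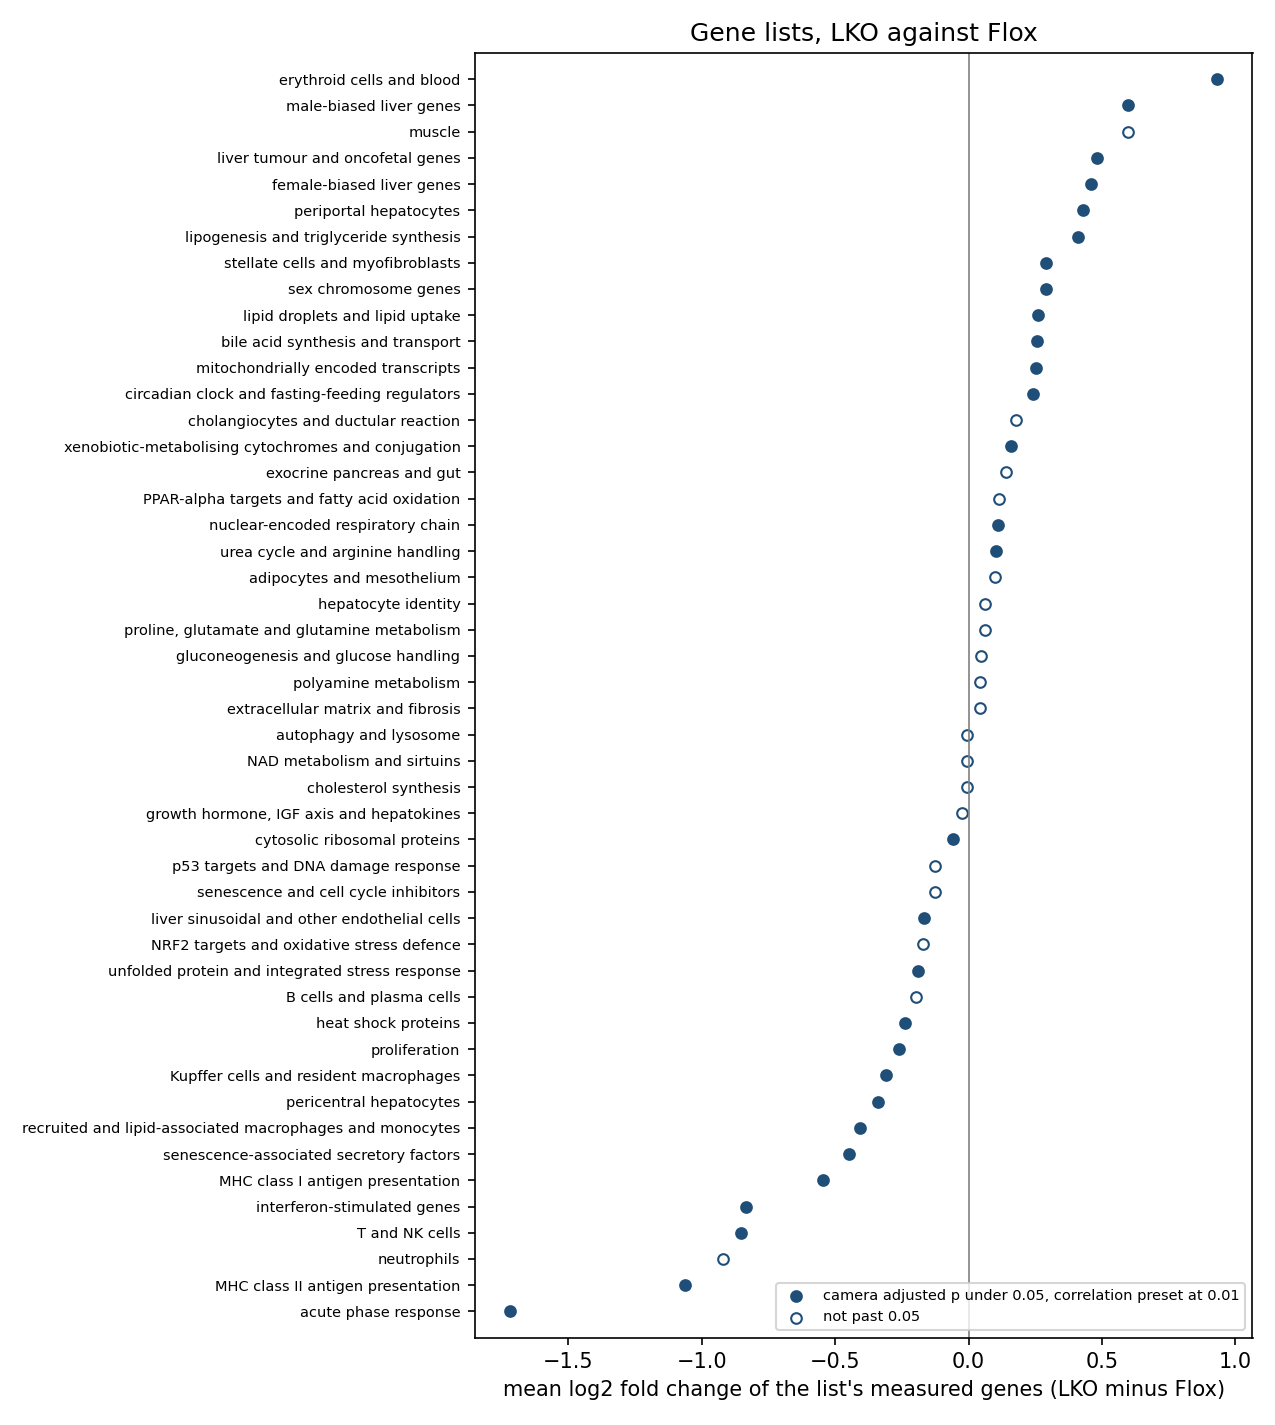
Mean log2 fold change (LKO minus Flox, horizontal axis) of the measured genes of each of the 48 lists. Filled points mark the 29 lists past camera's adjusted p of 0.05 with the correlation preset at 0.01, from -1.72 for the acute phase list to 0.93 for the erythroid list; with an estimated correlation 0 lists passed.

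Among lists that did not pass, the mean, the median and camera's direction differed in sign for NRF2 targets, NAD metabolism, the growth hormone axis, adipocytes and mesothelium, senescence inhibitors, proline metabolism, matrix, cholesterol synthesis and autophagy.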

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

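The tests of immune cell number, blood, the clock, the size of the acute phase difference, the list scores without Flox libraries 2 and 3 and other splits for genes past the threshold were chosen only after the result was seen, as was the fit without Flox libraries 2 and 3. Of 310 sets of 5 libraries of 1 group examined, 12 held a library far from the others, its gap to the nearest being above 0.71 of the range, and chance alone gives about 1 in 20. LKO column 1 was lowest in genes detected (0.739 of the range), Top2a (0.755), Slc40a1 (0.812) and Il2rb (0.780). Flox 3 was lowest in Bdh2 (0.759) and highest in Slc1a2 (0.868) and H2-Eb1 (0.809). LKO column 4 was highest in Arg1 (0.727) and lowest in Ddit3 (0.769), LKO column 5 was highest in Map1lc3b (0.774) and lowest in Krt19 (0.738), and Flox 2 was highest in Ddx3y (0.808).

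Acute phase, interferon-stimulated, MHC and T and NK cell genes were lower in LKO together. Libraries Flox 2 and 3, with high acute phase transcripts, as the whole source cannot be told apart from a difference between the groups: without them 5 of the 5 lists stayed lower and past camera's threshold with the preset correlation, a bound written before that fit but on libraries picked from the acute phase values, and the list scores overlapped between the groups in 5 of 5 (exact permutation p = 0.0714 to 0.696). Those libraries may set most of the size of the acute phase difference, since without them its mean log2 fold change was 0.28 of that with them (-0.48 against -1.72). Flox 4, which was kept, had the highest score of the remaining libraries in each of the 5 lists. For acute phase Flox 1 and 5 scored 7.43 and 7.04 (LKO mean 7.61). For T and NK cells they scored -1.34 and -0.89 (LKO mean -1.23). In the other lists both lay above the LKO mean. Flox 2 lay below the Flox mean in the interferon and MHC lists. The fit without Flox 2 and 3 therefore cannot decide whether single high Flox libraries are the source. Fewer immune cells of every kind in LKO and a change within cells cannot be told apart. The mean log2 fold changes of the 5 immune cell lists spanned 0.72, from -0.92 for neutrophils to -0.20 for B and plasma cells. By list score, another measure, the differences between the groups were -0.49 for neutrophils and 0.01 for B and plasma cells, and the SE of such a difference reached 0.82. An effect of the deletion stays open, although no list passed with an estimated correlation and, with 2 surrogate variables, the calls of the acute phase (0.128), MHC class I (0.147) and T and NK cell lists (0.151) ended.

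Erythroid genes were higher in LKO, while Atoh8, Id3 and Hamp, targets of BMP-SMAD signalling in hepatocytes, had lower values. More blood in the LKO pieces and more erythroid cells in the liver cannot be told apart as sources of the first, since both keep the ratio of Hba-a1 to Hbb-bs: the SD of its log2 was 0.19 of that of Hbb-bs (0.15 against 0.79). The platelet genes Pf4 and Ppbp, which blood would also bring and which are themselves members of the list, had log2 fold changes of 0.20 ± 0.27 and 0.88 ± 0.44 (SE). Lower BMP-SMAD output cannot be told apart from other causes of the second, as 5 targets not used to find the pattern (Id1, Id2, Smad6, Smad7 and Bambi) had a mean log2 fold change of -0.31 with a fry p of 0.127. With the erythroid score as a covariate the mean of Atoh8, Id3 and Hamp went from -0.97 to -0.70, or 0.72 of its size, Hamp going from -0.86 to -0.33, Atoh8 from -0.98 to -0.63 and Id3 from -1.08 to -1.12. The erythroid score itself was higher in LKO, so this fit cannot cleanly separate the score from the group.

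Clock genes differed widely between libraries of 1 group: log2 CPM of Dbp, a clock output, was -0.25, 0.78 and 1.0 in Flox 1 to 3 and 5.56 and 6.51 in Flox 4 and 5. The clock score is the mean log2 CPM of Arntl, Npas2 and Clock minus that of Dbp, Per3 and Ciart. It was 4.37 to 5.06 in Flox 1 to 3, 3.69 in LKO column 1 and -4.13 to 0.57 in the other libraries. The groups thus differed in their mix of scores. Of 8 other clock outputs, 5 passed the adjusted threshold for the clock score in the expected direction, among 61 genes that did. Such outputs would follow the score whatever shifted the clock. Collection at different phases of the clock or of feeding therefore cannot be told apart from other causes. Cdkn1a, a cell cycle inhibitor of the senescence list, had a log2 fold change of -1.29 between the groups and -0.46 with the clock score as a covariate. Its change of 0.98 per SD of the score did not pass (adjusted p = 0.0532). No biological explanation of the clock differences was tested.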

How the results depend on the processing

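The fits without Flox libraries 2 and 3, with an acute phase, clock or erythroid score, with 2 surrogate variables and with the column number as a block were chosen only after the data were seen. Of 2573 values of 104 results for named genes under the alternatives, 2554 kept their direction and side of the threshold, and of 1246 values for the 48 lists 952 did. For the genes this says little, since none passed the full comparison and every gene fit but DESeq2 also called 0. Many were also named for their small p-values in these data. DESeq2 called 4 genes higher and 6 lower, where edgeR called 0 and 0. The 29 lists became 18 with limma-voom, 0 with an estimated correlation, 0 with fry, 14 with the acute phase score and 15 with 2 surrogate variables, and 18 to 31 with 1 library left out; the estimated correlations, with a median of 0.3, lie above the preset 0.01, and for the others the cause was not tested. The directions below turned, given as adjusted p, and the cause was not tested. With the acute phase score these were the lists of urea cycle (0.930), proline (0.636), senescence inhibitors (0.694), lipogenesis (0.440), lipid droplets (0.758), cholesterol (1.29e-06), PPAR-alpha (0.0194), glucose (0.469), unfolded protein (0.0375), heat shock (0.889), NRF2 (0.585), xenobiotic (0.542), mitochondrial (0.832), stellate (0.293), Kupffer (0.585), neutrophil (0.0658) and growth hormone genes (0.609), and the log2 fold changes of Mt2 (0.10), Mt1 (0.37) and Lcn2 (0.07). With 2 surrogate variables they were senescence inhibitors (0.689), secreted senescence factors (0.935), lipid droplets (0.764), cholesterol (0.00304), PPAR-alpha (0.00117), glucose (0.932), unfolded protein (0.701), NRF2 (0.841), xenobiotic (0.689), mitochondrial (0.791), respiratory chain (0.699), proliferation (0.349), stellate (0.935), Kupffer (0.00117), recruited macrophages (0.701), neutrophils (0.00487), B cells (0.750), growth hormone (0.689) and NAD (0.985), and the log2 fold changes of Mt1 (0.22) and Lcn2 (0.05). Without Flox 2 and 3 they were proline (0.578), lipogenesis (0.876), cholesterol (5.23e-09), glucose (0.876), unfolded protein (0.0380), NRF2 (0.646), xenobiotic (0.690), stellate (0.656) and growth hormone (0.876). With the erythroid score they were autophagy (0.520), matrix (0.287), B cells (0.287) and adipocytes (0.117), and the log2 fold changes of Lpl (-0.38), Angptl4 (0.08) and Ighg1 (2.79). With the clock score they were proline (0.720), cholesterol (0.334) and adipocytes (0.785), and with limma-voom proline (0.850) and cholesterol (0.287). Calls that ended without turning were, with limma-voom, those of urea cycle (0.0810), secreted senescence factors (0.106), lipid droplets (0.123), unfolded protein (0.474), heat shock (0.0683), xenobiotic (0.139), mitochondrial (0.118), proliferation (0.0902), tumour (0.152), stellate (0.172) and Kupffer cell genes (0.130). With the acute phase score they were secreted senescence factors (0.585), bile acid (0.610), clock (0.364), respiratory chain (0.930), ribosomal (0.324), proliferation (0.679), tumour (0.316), recruited macrophages (0.585) and female-biased genes (0.474), and with the clock score urea cycle (0.0679), lipid droplets (0.0797), unfolded protein (0.361), heat shock (0.120), xenobiotic (0.0797), tumour (0.148) and stellate genes (0.0797). With the erythroid score they were pericentral (0.319), ribosomal (0.193), tumour (0.287), male-biased (0.346) and sex chromosome genes (0.135). With 2 surrogate variables they were urea cycle (0.750), acute phase (0.128), MHC class I (0.147), lipogenesis (0.104), bile acid (0.553), heat shock (0.689), ribosomal (0.151), endothelial (0.193), T and NK cell (0.151) and female-biased genes (0.161). Without a filter they were urea cycle (0.0530) and sex chromosome genes (0.120), with library totals secreted senescence factors (0.0767), proliferation (0.0810) and Kupffer cells (0.0810), and with the block endothelial genes (0.0514). Calls gained in the direction of the full comparison were, with the erythroid score, those of cholesterol (0.00708), PPAR-alpha (7.64e-11), glucose (0.000225) and neutrophils (1.25e-08). Others were matrix without Flox 2 and 3 (0.00296), with the acute phase score (0.000158) and with 2 surrogate variables (0.0251), adipocytes with 2 surrogate variables (0.000969), and B cells without Flox 2 and 3 (0.00162) and with the clock score (0.0358). With the block they were PPAR-alpha (0.0453) and glucose (0.00546), and without a filter glucose (0.0240). At a threshold of 0.10 glucose (0.0584), neutrophils (0.0584) and muscle (0.0973) passed too. The 1193 genes at an unadjusted p under 0.05 became 2043 without a filter, 2175 with the erythroid score, 786 with 2 surrogate variables, 517 without Flox 2 and 3 and 455 with the acute phase score. B cells turned without a filter (0.786), with library totals (0.813) and with the block (0.818), autophagy without a filter (0.980) and matrix with library totals (0.988). With 1 library left out, lists that turned ranged over 0.552 to 0.931 for proline, 0.504 to 0.965 for senescence inhibitors, 0.000143 to 0.937 for cholesterol, 0.0190 to 0.937 for PPAR-alpha, 0.539 to 0.951 for autophagy, 0.191 to 0.993 for matrix, 0.00026 to 0.861 for Kupffer cells, 0.179 to 0.966 for B cells, 0.271 to 0.981 for adipocytes and 0.312 to 0.990 for growth hormone, and the log2 fold change of Cela1 over -0.09 to 0.21. Whether the column numbers pair the libraries cannot be told from these values. Deviations of same-numbered libraries correlated at 0.35, 0.09, 0.07, 0.10 and 0.29, with the best partner of the same number for columns 1 and 5 alone. The clock score was 5.06 in Flox 1 and -2.76 in Flox 5, and 3.69 in LKO column 1 and -4.13 in column 5. The replicate block left 0 genes higher and 0 lower (1535 at an unadjusted p under 0.05, against 1193 without it) and 30 lists. Depth limits Arg2, with 9 and 10 counts per group, whose log2 ratio of 0.25 ranged over -0.71 to 1.07 with 1 library left out.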

Other observations

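The counts of splits for genes past the threshold and for each list by itself were chosen only after the result was seen; the other 2 counts of splits were planned before it. Of 126 possible splits of the 10 libraries into 5 and 5, 100 were drawn, the real one included. For genes past edgeR's adjusted threshold the real split gave 0, so that 100 of 100 gave as many by construction and the count says nothing of chance; the highest other gave 33. For genes at an unadjusted p under 0.05 chance cannot be excluded, as 14 of 100 splits gave at least the real 1193, with 2680 as the highest other. For the number of lists past camera with the preset correlation, 3 of 100 splits gave at least the real 29, with 30 as the highest other. That share lies under the 0.05 bound set beforehand, but splits that mix the groups reached this number too, so chance is not excluded. The median split gave 16 lists, and each of the 29 lists called passed in 18 to 65 of the 99 other splits (median 49), among them acute phase in 65, interferon-stimulated genes in 64, periportal genes in 43 and erythroid genes in 43. Chance is therefore not excluded for any 1 of these lists by this test, and with an estimated correlation the real split gave 0 lists while 2 others gave 1 each.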
